A study of Mus musculus with 2 samples.

How the data were processed

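Total RNA was extracted from 1 WT and 1 Foxj3 KO myoblast culture, biotin-labelled cRNA was prepared and each sample was hybridised to 1 array, per the labels' protocols. The value table as deposited by the authors holds 1 linear signal intensity per probe set and array, never below 0. The algorithm that summarised probes into probe sets and the scaling of the arrays were not given in the sources used here. The means without the top and bottom 2% of values were 126.117 on the WT array and 125.528 on the KO array, within 5% of each other, so the values were used as deposited. The scanner record of each array, per the file headers, had 42 fields, of which 40 were identical between arrays; the arrays shared hybridisation time, scan day and array lot. Control probe sets, if any, were left out when the table was read. A planned comparison of 3' to 5' control signals as a check of RNA quality was not run. The number of columns left without a sample was 0.

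Probe sets were named through the platform annotation, which can be old, and symbols were brought up to date through Entrez identifiers in a RefSeq gene table (assembly GRCm38.p6, used for names and gene order only). Of 45037 probe sets, 34945 had 1 symbol, 932 had several and 9160 were not listed; 34741 of the first had their Entrez identifier in the gene table. Probe sets with several symbols or none named no gene. The array build and the positions of probes were not used here.

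The detection floor was the 40th percentile of the pooled values of both arrays, 47.04. Values under it were set to it before log2. A gene was represented by the probe set with the highest mean log2 value and counted as measured if over the floor on at least 1 array. Where 1 array was under the floor, the ratio is a bound and is given as "at least N-fold". Direction is always KO over WT. With 1 array per group no test was possible, no p-value was computed, and a fixed threshold of 2-fold was used to count genes. Technical spread was described by the agreement of different probe sets of 1 gene, which leaves out differences between cultures and animals. Other probe sets are those over the floor on at least 1 array.

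There were 25 gene lists fixed before the data were examined: myogenic regulators, myoblast and satellite cell markers, sarcomere and differentiated muscle, slow fibre genes, fast fibre genes, cell cycle G1/S and DNA replication, cell cycle G2/M and mitosis, CDK inhibitors and p53 targets, forkhead factors, fibroblast and extracellular matrix, smooth muscle and pericyte markers, adipogenic markers, endothelial markers, macrophage and leukocyte markers, Schwann and neural markers, oxidative phosphorylation, glycolysis, cholesterol biosynthesis, interferon response, TGF-beta and BMP response, imprinted growth genes, Hox genes (with T-box genes and Pitx1), sex-linked genes, stress and unfolded protein response, and ribosomal proteins. The rule for the neighbours of Foxj3, the 20 measured genes on each side, was fixed with them, for 26 lists in all. The median log2 ratio of a list was placed among 10000 random lists of the same size, drawn from 20 bins of mean log2 value to match its brightness. This percentile describes these 2 arrays and is not a p-value.

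Genes to be named were also fixed beforehand: Foxj3 with all its probe sets; 11 genes whatever their value (Mef2c, Myod1, Myf5, Myog, Pax7, Mef2a, Mef2d, Foxk1, Foxj2, Cdkn1a, Cdkn1b); the 15 largest and 15 smallest log2 ratios among genes over the floor on both arrays; the 5 brightest genes in each direction that were under the floor on 1 array and at least 4 times the floor on the other; up to 4 members of each list with the largest ratios of at least 2-fold, or the 2 largest if none reached it; and all measured sex-linked genes. Predicted transcripts were counted and not named. Genes named outside this rule are marked where they appear.

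The calculation was tested on simulated data with 13962 genes, of which 200 were given known log2 ratios with noise of SD 0.2. All genes at log2 ratios of 2 and -2 (50 each) were called, and 96% of those at 1.5 and -1.5. Of random lists of 30 genes, 4% lay outside the limits, and their median percentile was 39.15. The changed genes were bright ones, and all probe sets of a gene were shifted together. In the data the log2 ratios of probe sets of a gene had an SD of 0.62 per probe set. The simulation therefore checks the calculation and not how often genes are called rightly in these data.

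Alternatives fixed before the data were examined were quantile, median and loess scaling (span 0.3), floors at the 20th and 60th percentiles, no floor, a pseudocount equal to the floor, the mean over probe sets, leaving out probe sets that match several transcripts (names ending in _s_at or _x_at), thresholds of 1.5-fold and 3-fold, calls restricted to genes whose other probe sets shared the sign, list members under the floor set to 0, and random lists not matched on brightness. Subtracting the median ratio of probe sets with neighbouring identifiers, and using only probe sets designed from RefSeq, full-length or curated complementary DNA accessions (those starting with NM_, BC or AK), were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.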

Results

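Gene expression was measured in cultured mouse skeletal myoblasts, the dividing precursors of muscle fibres, with and without a working Foxj3 gene, which encodes a forkhead transcription factor. RNA of 1 wild-type (WT) culture and 1 Foxj3 knockout (KO) culture, both at passage 3 and harvested before confluence in growth medium, was hybridised to 1 Affymetrix oligonucleotide array each. The comparison asks which transcripts differ between myoblasts with and without Foxj3. There were no replicates, so no difference could be set against a spread between cultures, and every value describes these 2 arrays. The deposited intensities covered 45037 probe sets, with a median of 62.03 on the WT array and 63.94 on the KO array, and 59.2% and 60.8% of probe sets lay over the detection floor of 47.04. Of 18193 genes with a named probe set, 14597 were over the floor on at least 1 array. The number of arrays limits the precision of every value.

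Foxj3 itself was lower in the KO library by its brightest probe set. This probe set, 1435362_at, read 495.51 on the WT array and 77.28 on the KO array, 6.41-fold lower (log2 ratio -2.68). The probe set 1438220_at read 79.74 and 99.40 (log2 ratio 0.32), and 1459055_at was under the floor on both arrays. Which part of the gene the knockout removed, and which of these probe sets lie in it, was not given in the sources used here. The measured probe sets differed in direction, so they do not settle whether the labels are right. Averaged over its probe sets, the log2 ratio was -0.79, a mean in which 1459055_at, under the floor on both arrays, counts as 0.

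Several genes of muscle contraction were among the most strongly lower genes in the KO library. Tnni3, the cardiac form of troponin I, was the brightest probe set of the WT array at 24578 and read 92.58 on the KO array (log2 ratio -8.05). This value came from 1 probe set and could not be checked against another. Its ratio stood far apart from all others, and a faulty signal was not excluded. Mymx, which encodes a small membrane protein needed for myoblast fusion, was 15.7-fold lower in the KO library, the slow myosin heavy chain Myh7 12.9-fold lower, the fast troponin T Tnnt3 10.4-fold lower and the embryonic myosin heavy chain Myh3 9.89-fold lower. Srl (10.3-fold), Tnnc1 (9.39-fold), Myl4 (9.14-fold), Smpx (8.90-fold), Zfp593 (7.53-fold), Myom1 (7.49-fold), Tmem158 (7.17-fold), Myom2 (7.03-fold) and Ccdc141 (6.55-fold, with 1 of its 5 other probe sets of opposite sign) were also lower. Hspb8, a small heat shock protein gene, was 8.09-fold lower by its main probe set, while 1 of its 2 other probe sets had the opposite sign. Among genes under the floor on the KO array alone, Tnnc2 was at least 11.9-fold lower, Myh8 at least 11.8-fold, Cavin4 at least 10.9-fold and Lmod3 at least 9.05-fold. Erbb3, a neuregulin receptor, was at least 13.4-fold lower by its main probe set, but its other probe set had a log2 ratio of 0.26.

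In the other direction, Cap1, a regulator of actin filaments, read 63.30 on the WT array and 848.80 on the KO array, 13.4-fold higher, and its second probe set read 5.50 and 498.71. Treml2 was 10.6-fold higher in the KO library, the homeobox gene Tlx3 10.1-fold, the mitochondrial gene ND5 7.69-fold, St6galnac1 6.27-fold, the receptor tyrosine kinase Axl 5.75-fold (log2 ratio 0.24 at its other probe set) and the transcriptional repressor Tgif1 5.13-fold. Tbxa2r (5.06-fold), Plagl1 (4.96-fold), Rpl27a (4.82-fold) and Rnf111 (4.63-fold) followed. Ptprj, Lgr6, Pabpc1 and Dus3l were 5.27-fold, 4.90-fold, 4.66-fold and 4.63-fold higher by their main probe sets, and in each the other probe set had the opposite sign, with log2 ratios of -0.01, -1.07, -1.02 and -0.45. The genes under the floor on the WT array alone included Exosc6, which read 0.43 and 857.83 and was at least 18.2-fold higher, Camk2b (at least 16.4-fold), Disp2 (at least 15.98-fold, with 1 of its 2 other probe sets of opposite sign), Spata2l (at least 9.11-fold) and Agtpbp1 (at least 5.46-fold, with a log2 ratio of -0.59 at its other probe set). On the WT array Camk2b, Spata2l and Disp2 read 0.92, 1.91 and 2.41, near 0 like Exosc6. Faulty signals were not excluded for these genes, and Exosc6, Camk2b and Spata2l had no other probe set to check them.

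**Figure D1:**
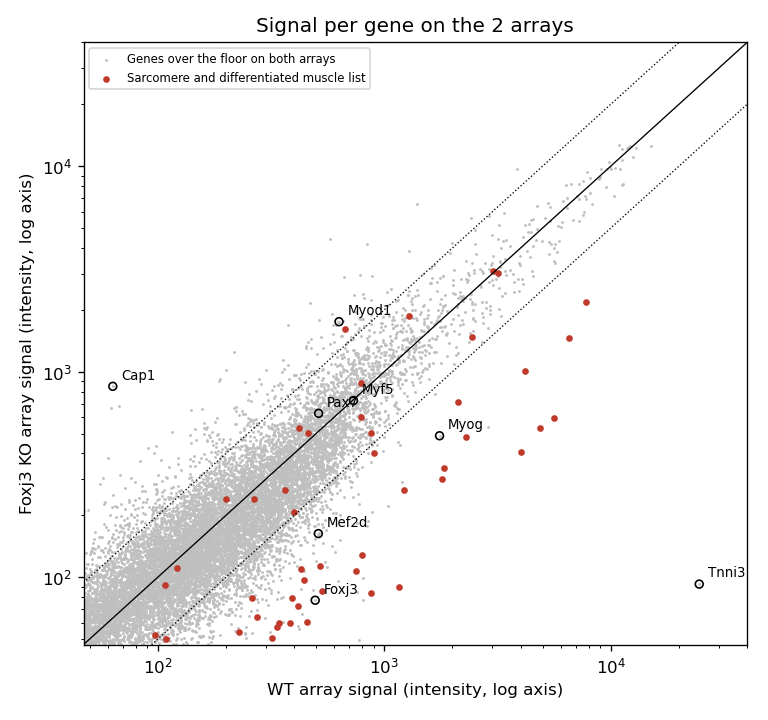
Signal of each gene over the floor on both arrays, WT on the horizontal and Foxj3 KO on the vertical axis, both intensities on log axes. The solid line marks equal signal and the dotted lines 2-fold differences. Red points are members of the sarcomere and differentiated muscle list, and circled genes are named. Tnni3 sits at 24578 on the WT array against 92.58 on the KO array, and most red points lie under the lower dotted line.

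Counted over all genes, 544 were at least 2-fold higher in the KO library and 981 at least 2-fold lower, so 64.3% of these genes were lower. The share was 58.7% with quantile scaling (594 and 843), 56.9% with loess scaling (612 and 809) and 52.3% with both arrays set to the same median (705 and 773). Lower genes stayed in excess under every scaling, and the size of the excess depended on the scaling. Of the higher genes 119, and of the lower genes 181, were under the floor on 1 array, so that their ratios are bounds. Across the 12397 genes over the floor on both arrays, the log2 signals of the arrays had a Pearson correlation of 0.879, which is across genes that are not independent replicates.

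Probe sets of the same gene often disagreed, and this is the only measure of technical spread in the data. Among 4752 genes with 2 probe sets over the floor on both arrays, both log2 ratios had the same sign in 53.9% (95% Wilson interval 52.5% to 55.3%), and the differences between them had an SD of 0.88. Probe sets of a gene that did not differ between the arrays can have either sign, so this share is not a rate of error. Of the 234 genes called at least 2-fold higher that had other probe sets, 112 (47.9%) had all of them above 0. Of the 491 such genes called at least 2-fold lower, 218 (44.4%) had all of them below 0. At least 1 other probe set reached 2-fold in the called direction in 43 (18.4%) of the higher and 81 (16.5%) of the lower genes. Averaged per gene, the other probe sets had median log2 ratios in the called direction of 0.12 (higher) and 0.09 (lower). The main probe sets of these genes had median sizes of 1.29 and 1.22. Most of these calls were therefore not reached by another probe set. Among 5526 genes under 2-fold with other probe sets, all shared the sign of the main one in 39.2%. Of 100 named genes at least 2-fold different, 46 had other measured probe sets. In 23 of these at least 1 had the opposite sign, and in 10 all were at least 2-fold with the same sign. In the remaining 13 at least 1 had the same sign but was under 2-fold, with log2 ratios of 0.24 for Axl, 0.23 for Plagl1, 0.22 for Sdc4, 0.18 for Xaf1, 0.53 for Ybx1, -0.47 for Bgn, -0.82 for Hoxd8, -0.68 and -0.37 for Mef2c, -0.29 for Myl4, -0.56 for both Ndufa5 and Tmem158, -0.05 for Pdk1 and -0.9996 for Zfp593. With the mean over probe sets, where those under the floor on both arrays count as 0, 30 of 99 named genes other than Foxj3 came under 2-fold. Of these 6 had no other measured probe set, with means of 0.85 for Treml2, 0.74 for Myod1, -0.50 for Cyp51, -0.47 for Fabp4, -0.997 for Myh11 and -0.84 for Rps6. A 2-fold ratio of a single gene is therefore about as large as the difference between its probe sets.

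Genes of the sarcomere and of differentiated muscle were lower in the KO library as a group. Of 57 measured members, 50 had ratios below 0, 39 were at least 2-fold lower and 1 was at least 2-fold higher. The median log2 ratio was -2.08, a 4.23-fold lower signal, and lay below all 10000 random gene lists matched on brightness (percentile 0), whose 95% range was -0.21 to 0.15. Beside the genes above, the skeletal actin gene Acta1 read 7809 and 2188, the fast myosin light chain Mylpf 6529 and 1455, and Ttn, which encodes titin, 904 and 403. The single member at least 2-fold higher was Mb, which encodes myoglobin, at 668 and 1620 by its brightest probe set, while another read 411 and 60.1. Tpm2 (3171 and 3006) and the acetylcholine receptor subunit Chrna1 (3029 and 3104) were close on both arrays, while Chrnb1 read 419 and 530. Tpm1 read 1281 and 1860 by its brightest probe set. Its other measured probe sets read 643 and 2295, 85.8 and 205, and, in the other direction, 383 and 119. These last members, and Acta1, Mylpf, Ttn and Mb, were chosen after their values were seen.

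Slow and fast fibre genes were both lower in the KO library. The slow list had a median log2 ratio of -1.92 over 14 measured genes, with 9 at least 2-fold lower and 1, Mb, at least 2-fold higher. The fast list had a median of -2.24 over 14, with 9 at least 2-fold lower. Slow genes included Myh7, Tnnc1, Myoz2 (6.28-fold lower) and Casq2 (6.25-fold lower). Fast genes included Tnnc2, Tnnt3, Actn3 (6.52-fold lower) and Tnni2 (6.18-fold lower). The difference of the medians, slow minus fast, was 0.32 and lay at percentile 61.4 when the genes were reassigned at random to both lists, with a range of -1.40 to 1.37. Each list shares 10 measured genes with the sarcomere list, so these results are not independent of it.

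The regulators of myogenesis differed in direction. Mef2c, which encodes a transcription factor of muscle differentiation, read 403.70 on the WT array and was under the floor on the KO array, at least 8.58-fold lower, and all 4 of its other probe sets were below 0. Myog, which encodes myogenin, was 3.60-fold lower (1754 and 488). Myod1, a determination factor of the myogenic lineage, was 2.77-fold higher (631 and 1751), and Myf5 was level at 731 and 724. Pax7, a marker of satellite cells, read 513 and 627 (log2 ratio 0.29), and 68.95 and 166.62 (1.27) by its other probe set. Mef2d was 3.14-fold lower, with 1 of its 2 other probe sets of opposite sign, and Mef2a read 825 and 509 by its main probe set while its 3 other measured probe sets were higher in the KO library, with a mean log2 ratio of 0.84. Eya4 was 3.01-fold lower by its main probe set, with 2 other probe sets of opposite sign. Over 30 measured members of the list of myogenic regulators, 1 was at least 2-fold higher and 6 at least 2-fold lower, and the median of -0.17 was at percentile 15.9.

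**Figure D2:**
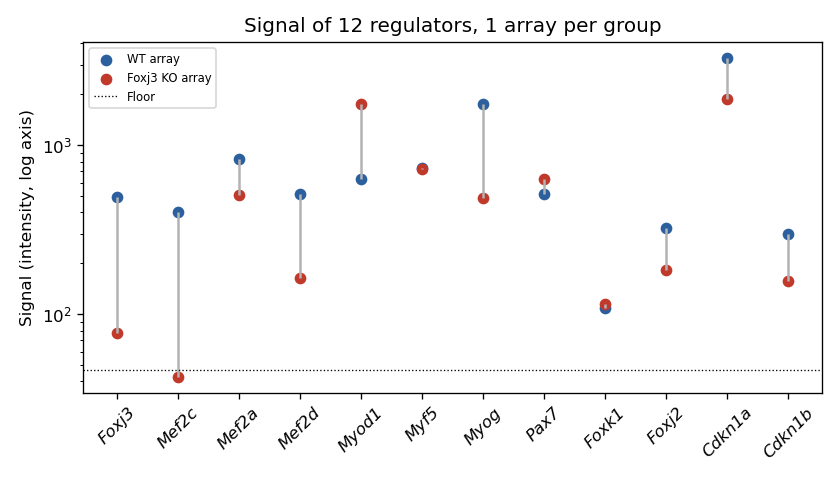
Signal of 12 regulators on the WT array (blue) and the Foxj3 KO array (red), 1 array per group, as intensities on a log axis, with the detection floor of 47.04 as a dotted line. Each gene is shown by its main probe set. Myog is lower and Myod1 higher on the KO array, and Mef2c is under the floor there.

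Markers of myoblasts and satellite cells had no common shift. Over 26 measured members the median log2 ratio was 0.07 (percentile 82.8), with 3 at least 2-fold higher and 0 at least 2-fold lower, and its sign changed to -0.02 with quantile scaling. The higher members were Sdc4, a syndecan of satellite cells, at 4.59-fold (log2 ratio 0.22 at its other probe set), the integrin Itgb1 at 2.92-fold and Myod1. The list shares 3 measured genes with the myogenic regulators.

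Cell cycle genes showed no common shift of the size seen in muscle genes. The G1/S and DNA replication list had a median of -0.30 over 43 measured genes (percentile 3.79), with 0 at least 2-fold higher and 7 at least 2-fold lower, and its sign turned to 0.03 with only NM_, BC or AK accessions, an alternative chosen after seeing the data. Among these were Ung (at least 2.99-fold lower), Rpa2, Rfc1 and Mcm5 (2.77-fold, 2.56-fold and 2.43-fold lower), of which Rpa2 and Mcm5 had a second probe set of opposite sign, and Rfc1 had 1 of 2. The G2/M and mitosis list had a median of -0.09 over 49 (percentile 56.5), with 3 at least 2-fold lower: Mki67 (2.22-fold), Incenp (2.15-fold, with 2 of its 3 other probe sets of opposite sign) and Nuf2 (2.14-fold). Its sign changed with loess scaling. The CDK inhibitors and p53 targets had a median of -0.01 over 26 (percentile 51.9), a sign that turned with median scaling, and 2 were at least 2-fold higher, Mdm2 (2.29-fold) and Cdkn3 (2.18-fold). Cdkn1a, which encodes the CDK inhibitor p21, read 3263 and 1870, with a log2 ratio of 0.10 at its other probe set, and Cdkn1b, which encodes p27, read 296 and 158.

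Among metabolic genes, glycolysis and oxidative phosphorylation were slightly lower. Glycolysis genes had a median log2 ratio of -0.36 over 17 measured genes (percentile 1.30), led by Slc16a3, a lactate transporter (2.60-fold lower), and Pdk1, a kinase that inhibits pyruvate dehydrogenase (2.36-fold lower). Oxidative phosphorylation genes had a median of -0.15 over 50 (percentile 0.11), and 1 was at least 2-fold lower, Ndufa5 (2.54-fold). Against random lists not matched on brightness the percentiles were 4.19 and 15.6, so both results rested on the matching. Cholesterol biosynthesis genes had a median of -0.28 over 20 (percentile 14.3), with 5 at least 2-fold lower. These included Hmgcs1 (3.27-fold, with 1 of 3 other probe sets of opposite sign), Idi1 (at least 2.96-fold, with a log2 ratio of 0.10 at its other probe set), Cyp51 (2.81-fold) and Insig1 (2.63-fold).

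The medians of markers of other cell types that a myoblast culture could hold lay within 0.38 of 0. Fibroblast and extracellular matrix genes had a median of 0.17 over 44 measured genes (percentile 98.0). The percentile was 92.3 with quantile scaling and ranged from 90.6 to 99.8 over all alternatives. Of the members 4 were at least 2-fold higher, including Thbs1 (4.40-fold) and Col4a2 (2.54-fold). The 2 at least 2-fold lower were Bgn (2.89-fold) and Tcf7l2 (2.14-fold, with all 3 other probe sets of opposite sign). Smooth muscle and pericyte markers had a median of 0.04 over 14 (percentile 61.2), with Synpo2 4.97-fold lower (1 of its 2 other probe sets of opposite sign), Myh11 3.99-fold lower, Smtn 2.10-fold lower and Tagln 2.79-fold higher. Adipogenic markers had a median of -0.28 over 18 (percentile 13.5), with Fabp4 3.64-fold and Fasn 2.07-fold lower. Endothelial markers had a median of 0.38 over 11 (percentile 99.1), of dim genes such as Esam (at least 2.01-fold higher), and this median lay within the random range with other floors. Macrophage and leukocyte markers had a median of -0.20 over 13 (percentile 18.9), which turned to 0.04 with the floor at the 20th percentile or without a floor, with Spi1 at 123 and 62.0 and Cd14 at 83.2 and under the floor. Schwann and neural markers had a median of 0.15 over 12 (percentile 85.7), with Erbb3 the single member at least 2-fold lower.

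Imprinted growth genes were higher in the KO library. Of 17 measured members 15 had ratios above 0, 3 were at least 2-fold higher and 1 at least 2-fold lower, and the median log2 ratio of 0.58 lay above all 10000 random lists (percentile 100). Plagl1, a zinc finger gene, was 4.96-fold higher by an _x_at probe set (log2 ratio 0.23, under 2-fold, without _s_at and _x_at probe sets), Mest 2.63-fold and Grb10, an adaptor of insulin signalling, 2.04-fold, and Igf2, chosen after its value was seen, read 2524 and 4199. Meg3, a maternally expressed noncoding RNA, was 2.63-fold lower, with 7 of its 8 other measured probe sets of the same sign. The mean over its probe sets gave a log2 ratio of -0.56, under 2-fold. Over the other probe sets of 10 members, leaving out the main ones, the median was 0.06 (percentile 53.2).

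Stress and unfolded protein response genes had a median of -0.31 over 32 measured genes (percentile 0.60), with the transcription factors Atf3 (4.28-fold), Junb (2.14-fold) and Egr1 (2.12-fold) lower and Myc 2.23-fold higher, and the mean over probe sets gave -0.05. TGF-beta and BMP response genes had a median of 0.11 over 25 (percentile 88.3), with Tgif1 the 1 member at least 2-fold higher and 4 lower, among them the follistatin gene Fst (3.62-fold), Tgfb3 (2.97-fold) and Ccn2 (2.43-fold). Interferon response genes had a median of 0.17 over 30 (percentile 93.9), with Xaf1 2.47-fold and Ccl2 2.29-fold higher and Igtp at least 2.05-fold lower. Ribosomal protein genes had a median of -0.07 over 29 (percentile 6.99), a sign that turned with median scaling, and 1 member, Rps6, was 3.22-fold lower. Other forkhead genes had a median of 0.04 over 25 (percentile 78.0), a sign that turned under 4 alternatives, with Foxn4 2.35-fold higher, Foxk1 at 109 and 115 (60.67 and 122.23 by its other measured probe set) and Foxj2 at 323 and 182. The Hox list, which also holds T-box genes and Pitx1, had a median of -0.03 over 26 (percentile 52.4), a sign that turned with 3 of the scalings. In it Hoxa3 was 2.19-fold higher (1 of 2 other probe sets of opposite sign), and Hoxd8 and the T-box gene Tbx15 were 2.18-fold and 2.32-fold lower.

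Of the sex-linked genes, 4 were measured, with a median of 0.16 (percentile 72.2), which was -0.26 with the floor at the 60th percentile and -0.02 with the mean over probe sets. The Y-linked Eif2s3y read 378 and 202, Uty 141 and 118 (1 of its 3 other measured probe sets of opposite sign) and Kdm5d 60.9 and 90.4, so Y-linked transcripts were over the floor on both arrays, and Xist read 45.5, under the floor, and 71.0, with its other probe set of opposite sign. The 20 measured genes on each side of Foxj3 on its chromosome had a median of -0.03 (percentile 57.2), a sign that turned with median scaling. Of these 40 neighbours 3 were at least 2-fold higher, Cap1, Col9a2 (3.30-fold) and Ybx1 (2.12-fold), and 1 at least 2-fold lower, Elovl1 (4.18-fold, with 1 of its 3 other probe sets of opposite sign).

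**Figure D3:**
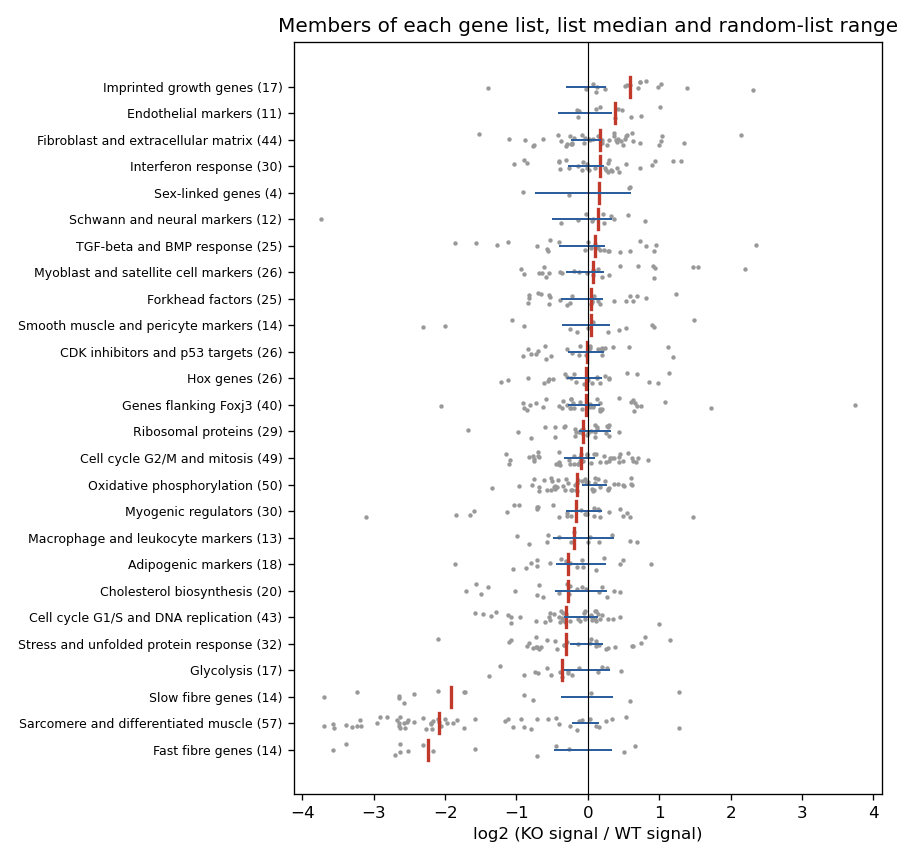
Log2 ratio of KO to WT signal for each measured member (grey points) of 26 gene lists, with the number of measured members in brackets, the list median (red bar) and the 95% range of medians of 10000 random lists matched on brightness (blue line). The sarcomere, slow fibre and fast fibre medians, -2.08, -1.92 and -2.24, lie far to the left of their random ranges, and the imprinted growth gene median, 0.58, lies to the right of its range.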

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

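All tests in this part, and the 3 patterns weighed, were chosen after the results were seen, and the deciding values of the noise tests and of the accession class test were replaced after earlier forms of them had been seen.

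A signal outside the gene comparison appeared in probe sets without a single gene symbol. Of 10092 such probe sets 5448 were measured, and 252 were at least 2-fold higher and 248 at least 2-fold lower in the KO library, with a lower share of 49.6%. Probe set 1440514_at, the brightest of the KO array, read 2779 on the WT array and 28909 on the KO array, and 1432947_at read 74.5 and 1367.

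The lower signal of muscle genes in the KO library was first set against technical and culture explanations. The tables argue against noise of single probe sets, since over the other probe sets of 19 sarcomere genes, leaving out the main ones, the median log2 ratio was -0.98, below all random lists (percentile 0), and 24 of 33 other probe sets (72.7%, 95% Wilson interval 55.8% to 84.9%) were below 0, 18 of 22 (81.8%) among the members at least 2-fold lower and 22 of 28 (78.6%) among those whose main probe set was below 0. The Wilson interval treats probe sets of 1 gene as independent, so it can be too narrow. A loss of myogenic cells as the whole cause would lower myoblast markers about as much. Their median lay 2.16 above that of the sarcomere genes (95% bootstrap interval over genes 1.42 to 2.52), which argues against it. A partial loss beside another cause was not excluded, since the test compares only the medians and other cells may express some markers. The fibroblast list median was 0.17 (percentile 98.0). It came within the 95% range of random lists under 5 of 13 alternatives, such as quantile scaling (percentile 92.3). Under the others it stayed above that range, up to 0.46 (percentile 99.8) with NM_, BC or AK accessions. Fewer cells that had left the cell cycle could not be decided, since the median of both cell cycle lists was -0.12 (percentile 38.8). A candidate explanation that stays open is that fewer KO cells had begun to differentiate, whether through the loss of Foxj3 or through a difference in density or handling between the 2 cultures, and with 1 culture of each genotype these cannot be separated.

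The disagreement between probe sets of a gene was set against several explanations. The shares with the same sign cover all pairs, of changed and unchanged genes. Probe sets of a gene that did not differ between the arrays can have either sign, so these shares cannot exclude a cause. Among pairs over 16 times the floor 61.0% had the same sign (254 pairs, interval 54.9% to 66.8%). The share grew from 53.9% over all pairs, and the correlation across genes from 0.13 to 0.47. Without probe sets that match several transcripts the share was 52.9%. Probe sets designed from NM_, BC or AK accessions had ratios higher than the other probe sets of the same genes by a median of 0.24 (1871 genes, 95% bootstrap interval 0.21 to 0.28). Pairs within that class had the same sign in 56.0%. Signals of a whole array paired with the wrong probe sets would leave the levels of 2 probe sets of a gene uncorrelated, but the correlations were 0.341 on the WT array (9010 genes, 95% bootstrap interval 0.317 to 0.363) and 0.416 on the KO array (0.390 to 0.439), which does not exclude wrong pairing of a part of the probe sets, and such a fault would alter gene values throughout. A difference between the labelled RNAs in how far they reach from the 3' end stays open, because probe positions and control probe sets were not used here, and no biological explanation was tested.

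The higher signal of imprinted growth genes was weaker evidence than its percentile of 100 implies. Over the other probe sets of 10 members the median was 0.060 (percentile 53.2), and 11 of 27 (40.7%) were above 0, 10 of 19 (52.6%) among members whose main probe set was above 0, and 4 of 4 (100%, 95% Wilson interval 51.0% to 100%) at Plagl1 and Grb10 (at Plagl1 as low as 0.23), the members at least 2-fold higher that had other probe sets. The median over other probe sets is what noise of single probe sets could give, while the last share speaks the other way but rests on 2 genes. These shares treat probe sets of 1 gene as independent, although 8 of the 27 belong to Meg3, so the interval can be too narrow. With only NM_, BC or AK accessions the median was 0.58 (11 genes, percentile 99.97), so the accession class alone is not the cause. The genotype stays open as an untested explanation.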

How the results depend on the processing

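The alternatives using probe sets of neighbouring identifiers or of NM_, BC or AK accessions were chosen after seeing the data. No leave-one-out fit was possible with 1 array per group. The medians of the sarcomere (-2.09 to -1.67), slow fibre (-2.08 to -1.31), fast fibre (-2.27 to -1.58) and imprinted (0.26 to 0.73) lists kept their sign and lay outside the random lists under every alternative. Counts of higher and lower genes moved from 544 and 981 to 1866 and 2811 at 1.5-fold, 109 and 221 at 3-fold, 330 and 490 with the mean over probe sets, 1537 and 1841 without a floor, 313 and 485 with a pseudocount and 315 and 435 with NM_, BC or AK accessions, and higher genes to 873 and 353 with floors at the 20th and 60th percentiles. Where any other probe sets had to share the sign they were 422 and 708, counts that keep genes without other probe sets. Among called genes that had other probe sets, 112 of 234 higher and 218 of 491 lower genes met this rule. The Foxj3 log2 ratio was -0.79 with the mean over probe sets, and probe set agreement was 52.3% (quantile), 52.4% (loess), 52.2% (no floor) and 56.0% (NM_, BC or AK). The endothelial median lay within the random lists at 0.093 and 0.13 (floors at the 20th and 60th percentiles), 0.17 (no floor), 0.30 (pseudocount), 0 (members under the floor at 0) and 0.42 (NM_, BC or AK), and the fibroblast median at 0.11 (loess), 0.11 (quantile), 0.0094 (members under the floor at 0), 0.14 (pseudocount) and 0.17 (identifier blocks). The stress median did so at -0.051 (mean), -0.081 (without _s_at and _x_at) and -0.20 (NM_, BC or AK), glycolysis at -0.22 (mean), -0.28 (NM_, BC or AK) and -0.36 (unmatched lists), and oxidative phosphorylation at -0.022 (NM_, BC or AK) and -0.15 (unmatched lists). Lists that passed the limits under a single alternative were G1/S at -0.30 (unmatched), although its median was -0.056 (percentile 51.45) without _s_at and _x_at and turned to 0.030 (percentile 73.05) with NM_, BC or AK, interferon at 0.25 (without _s_at and _x_at), smooth muscle at 0.53 (NM_, BC or AK) and ribosomal proteins at -0.042 (identifier blocks). Medians turned sign in 12 of 26 lists: Hox (7 of 13 alternatives), CDK inhibitors and p53 targets (6), forkhead (4), G2/M, Foxj3 neighbours, macrophage, ribosomal proteins and sex-linked (2 each), and G1/S, myoblast markers, myogenic regulators and smooth muscle (1 each). Log2 ratios of opposite sign were 0.98 for Elovl1 and 0.34 for Mcm5 (both without _s_at and _x_at, and with NM_, BC or AK), 0.18 for Incenp and 0.52 for Tcf7l2 (without _s_at and _x_at), 0.10 (20th percentile and no floor) and 0.064 (pseudocount) for Idi1, and -0.59 for Agtpbp1 and 0.0095 for Mef2d (NM_, BC or AK). The causes were not tested. For named genes, 1118 values stayed within the spread between probe sets, 51 moved beyond it and 11, of genes at least 2-fold different, reversed. Among genes under 2-fold 3 more values had the opposite sign, 0.31 (mean) and 0.95 (NM_, BC or AK) for Mef2a and 0.072 (median scaling) for Myf5. Signal over the floor left 11 of 21 listed endothelial genes.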

Other observations

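All tests in this part were chosen after the values were seen, and the bound that would exclude the hypothesis on the neighbours was moved from the upper limit of the runs to their median after the value had met the first bound.

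Among 25 gene families defined by their symbols, 24 had at least 3 measured genes and 4 lay outside the limits of matched random lists. For a test fixed beforehand 1.2 would be expected by chance. This test was chosen after the values were seen, so the count of 4 cannot be set against that number. Genes whose symbols start with Hsp, most of which encode heat shock proteins, were lower in the KO library, with a median log2 ratio of -0.47 over 25 genes (percentile 0.10) and of -0.47 over the 21 without Hspg2, Hspbp1, Hspbap1 and Hspb11 (percentile 0.13), led by the small heat shock genes Hspb8, Hspb2 (3.04-fold lower) and Hspb3 (2.39-fold lower), while Hspa12a was 3.01-fold higher. Mitochondrial ribosomal protein genes had a median of -0.36 over 76 genes (percentile 0.03), and 61 of them were below 0, with Mrps25 2.24-fold, Mrpl44 2.15-fold, Mrps34 2.12-fold and Mrpl48 2.02-fold lower. Kelch-like genes had a median of -0.35 over 27 (percentile 2.26), led by the muscle genes Klhl41 (6.17-fold lower) and Klhl40 (at least 5.79-fold lower). SR splicing factor genes had a median of 0.51 over 9 (percentile 98.7), with Srsf5 3.48-fold and Srsf6 2.12-fold higher. All 4 medians kept their sign under quantile, median and loess scaling. With only NM_, BC or AK accessions the mitochondrial ribosomal and Hsp medians were -0.28 (percentile 1.18) and -0.47 (percentile 0.47), while the Kelch-like and SR medians were -0.28 (percentile 13.9) and 0.26 (percentile 90.7).

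A hypothesis tested was that DNA of another strain, carried along with the targeted allele, might alter signals of the genes beside Foxj3. The log2 ratios of the 40 measured neighbours had an SD of 0.88, at percentile 97.46 of 13772 runs of 40 neighbouring genes, whose median SD was 0.62. Without Cap1 the SD was 0.66 (percentile 65.5 of the same runs). Those runs kept their own most extreme genes, so this percentile is too low for a like comparison. Much of the spread came from that 1 gene, and the hypothesis could be neither supported nor excluded. Both Cap1 probe sets were much higher in the KO library, at 63.3 and 849 and at 5.50 and 499.

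Values at or under 2.94 on 1 array and at least 188.16 on the other were found in 5 genes near 0 on the WT array and 1 near 0 on the KO array, while the arrays held 151 and 144 probe sets at 0. Those near 0 on the WT array included Exosc6 at 0.43 and 858, Camk2b at 0.92 and 770, Spata2l at 1.91 and 428 and Disp2 at 2.41 and 752.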
